A study of Mus musculus with 6 samples.

How the data were processed

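The series compared cells described as T-cell progenitors, grown from mouse embryonic stem cells (ESCs), with 3 arrays per genotype and 6 in all. The stem cells carried 1 disrupted copy of Gata3 (Gata3+/-) or no intact copy (Gata3-/-). Per the labels' protocols, the stem cells were differentiated on OP9 and OP9-DL1 stroma, bone marrow stromal cells of which the second kind carries the Notch ligand DL1, with the cytokines IL-7 and Flt3L added. Progenitors of the T lineage were then sorted by flow cytometry and their labelled cRNA was hybridised to Affymetrix arrays. The sort markers are not given in the sources used here. The genotype and replicate number of each array were taken from its title, which calls the replicates biological. The labels do not say whether they came from separate cultures or stem cell clones, so the p-values measure only the spread between these arrays.

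The values deposited by the authors were linear intensities for 45101 probe sets, between 2.28 and 77334.92. Per the labels, they were made with GC-RMA, which corrects background from the sequence of each probe and normalizes between arrays. GCOS, the Affymetrix operating software, is named in the submitters' processing notes. Versions, settings and the probe set definition are not given in the sources used here. The deposited medians lay between 8.57 and 8.93 on the 6 arrays. Low values form a floor under GC-RMA, so differences between dim probe sets carry little information.

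The log2 of each deposited intensity was taken here and no further normalization was applied. The 64 Affymetrix control probe sets were left out. A probe set was tested when its log2 value reached 4, an intensity of 16, on at least 3 of the 6 arrays, which left 20102. On each array, 19977 to 20124 probe sets reached that minimum, and 53.5% of probe sets stayed under it on all arrays. Where every array of a genotype lay under the minimum, the fold is given as a lower bound, from the mean of the brighter group against the minimum. The number of arrays limits the precision.

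Gene names came from the platform annotation, in which 34958 probe sets had 1 gene symbol, 932 had several and 9211 were not listed. Of the listed probe sets, 34754 were matched by gene identifier to a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table also gave the chromosome and the order of genes. No coordinates are given, because no build is named for the deposited values. Each gene was represented by the probe set with the highest mean over the 6 arrays, among those tested with 1 symbol, which gave 10302 genes. No other tested probe set of a named gene differed from it in sign.

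Differences were tested with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided), as Gata3-/- minus Gata3+/-. Adjusted p-values follow Benjamini and Hochberg over all probe sets tested, with a threshold of 0.05. Lists of genes were tested with camera (preset correlation between genes of 0.01, two-sided), adjusted over the 18 lists with at least 5 measured members out of 21 lists fixed. Camera, which compares a list with the other genes, was also run with an estimated correlation. Beside it fry was run, whose directional test sets a list against no change. Counts adjusted over the list alone are given beside counts over all genes. Plots were drawn with matplotlib version 3.10.9 in Python version 3.11.15.

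Groups, tests, lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule named Gata3, the 15 largest rises and 15 largest falls among genes past the threshold whose genotypes did not overlap, up to 4 called members of each tested list (or the 2 with the smallest p where no member was called), and a fixed set of regulators of blood development. Other genes are named as examples and were chosen after their values were seen. The alternatives were no filter, a stricter filter at a log2 value of 6, quantile normalization, median centring, a variance trend with robust eBayes, array weights, the replicate number as a block, a 2-fold minimum, averaging the probe sets of a gene, and leaving out each array in turn. The analysis by chromosome, the fits without chromosomes 6, 11, 14 and Y or without the arrays numbered 2, and 3 further gene lists were chosen after seeing the data.

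The procedure was tested on simulated data for the comparison of the 2 genotypes over 20102 probe sets, of which 100 were changed by a log2 value of 1 and 100 by a log2 value of 2. It recovered 54% of the former and 84% of the latter, with 9 false calls among 147. For lists, over 10302 genes, a log2 shift of -0.5 given to the cell cycle list was recovered, and 1 list that had not been shifted was called too. That shift was larger than the cell cycle list's median of -0.25 on the real arrays. It does not show that shifts of the smaller size are recovered. In both simulations the values were drawn independently for each probe set. Deviations that genes share on the real arrays were not simulated, so these rates need not hold for the real data.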

Results

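Gene expression was measured on 6 Affymetrix arrays, 3 labelled Gata3+/- and 3 labelled Gata3-/-. The cells, derived from mouse embryonic stem cells, are described as T-cell progenitors, although most T-lineage genes were not measurable, as given below. GATA3 is a zinc finger transcription factor needed for early T-cell development. The comparison asks how expression differs between cells with 1 intact copy of the gene and cells with none. Each array measured a sorted population as a whole. A difference can therefore lie in which cells were present or in expression within cells, and these were not separated. Levels are log2 GC-RMA intensities, given as mean ± SD with n = 3 arrays per genotype, and differences are Gata3-/- minus Gata3+/- with their standard error (SE). Correlations between arrays, across all tested probe sets, were 0.974 to 0.990 within a genotype and 0.956 to 0.982 between genotypes.

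The targeted gene itself showed no detectable difference. The probe set for Gata3 stood at 5.88 ± 0.50 in Gata3+/- arrays and 5.93 ± 0.48 in Gata3-/- arrays, a difference of 0.05 with a 95% interval from -0.80 to 0.89 (exact permutation p = 0.7, two-sided, where the smallest p possible is 0.1). Array probe sets lie near the 3' end of transcripts, and the labels do not give the disrupted part of the gene. This probe set therefore does not check the genotypes, which are used as labelled.

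Between the genotypes 543 of 10302 genes differed, 295 higher and 248 lower in Gata3-/- arrays. Siglech, a surface receptor of plasmacytoid dendritic cells, fell from 8.04 ± 0.85 to below the minimum on all 3 Gata3-/- arrays, at least 16.4-fold lower (adjusted p = 0.0281). Il12b, which encodes a subunit of the cytokine IL-12, rose from 5.13 ± 0.94 to 8.83 ± 0.38 (difference 3.70, SE 0.49, adjusted p = 0.0335). Ccr2, the chemokine receptor that guides monocytes, fell from 11.97 ± 0.35 to 10.18 ± 0.34 (difference -1.79, SE 0.24), while its 2 other tested probe sets, with differences of -1.94 and -0.19, did not pass. Il7r, the receptor chain for IL-7, rose from 9.33 ± 0.36 to 10.53 ± 0.06, and Kit, the receptor for stem cell factor, rose from 10.26 ± 0.25 to 11.22 ± 0.24.

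The largest rises were in genes of several kinds. Tenm2, a teneurin adhesion receptor of neurons, rose by a fitted 4.41 (SE 0.62) and Aard by a fitted 4.32 (SE 0.77). For these and for Myo5b, a myosin motor with a fitted difference of 3.48, 1 of 3 Gata3+/- arrays reached the minimum, so the fitted sizes and their rank depend on values near the floor. Cbln1, a secreted synapse organizer, was at least 4.27-fold higher, Gprin2 at least 5.25-fold, Calcb, a calcitonin gene-related peptide, at least 4.55-fold and Stxbp6 at least 3.96-fold. Differences were 3.56 for Serpinb9b, a protease inhibitor, 3.50 for Dscaml1, a cell adhesion molecule, and 3.21 for Flrt3, a membrane adhesion protein. The gap junction gene Gjb2 differed by 3.17, Nostrin by 3.06, the glycosyltransferase gene B3gnt5 by 2.91 and P2ry10, a G protein-coupled receptor of lymphoid cells, by 2.78. For Serpinb9b, Dscaml1, Gjb2 and B3gnt5, 2 of 3 Gata3+/- arrays reached the minimum.

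The largest falls were likewise in genes of several kinds. Slco2b1, an organic anion transporter, fell by 3.02 (SE 0.32) and Fcrls, an Fc receptor-like gene, fell from 10.42 ± 0.09 to 7.74 ± 0.34. Ccl12, a chemokine that attracts monocytes, fell by 1.89 (SE 0.26), Tmem176b by 2.04 (SE 0.29), Naaa, a lysosomal amidase, fell by 1.88 and Dram1, a lysosomal protein, fell by 1.96. Rnase4, a secreted ribonuclease, fell by 2.05 from a level of 13.13 ± 0.17. Flt1, a VEGF receptor, was at least 3.54-fold lower, Cd28, a T-cell costimulatory receptor, at least 2.32-fold and the immunoglobulin segment Ighv14-2 at least 3.05-fold. Bach2, a transcriptional repressor of lymphocytes, fell by 2.12, Aplnr, the apelin receptor, by 2.07 and the predicted gene Gm9054 by 1.94.

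**Figure D1:**
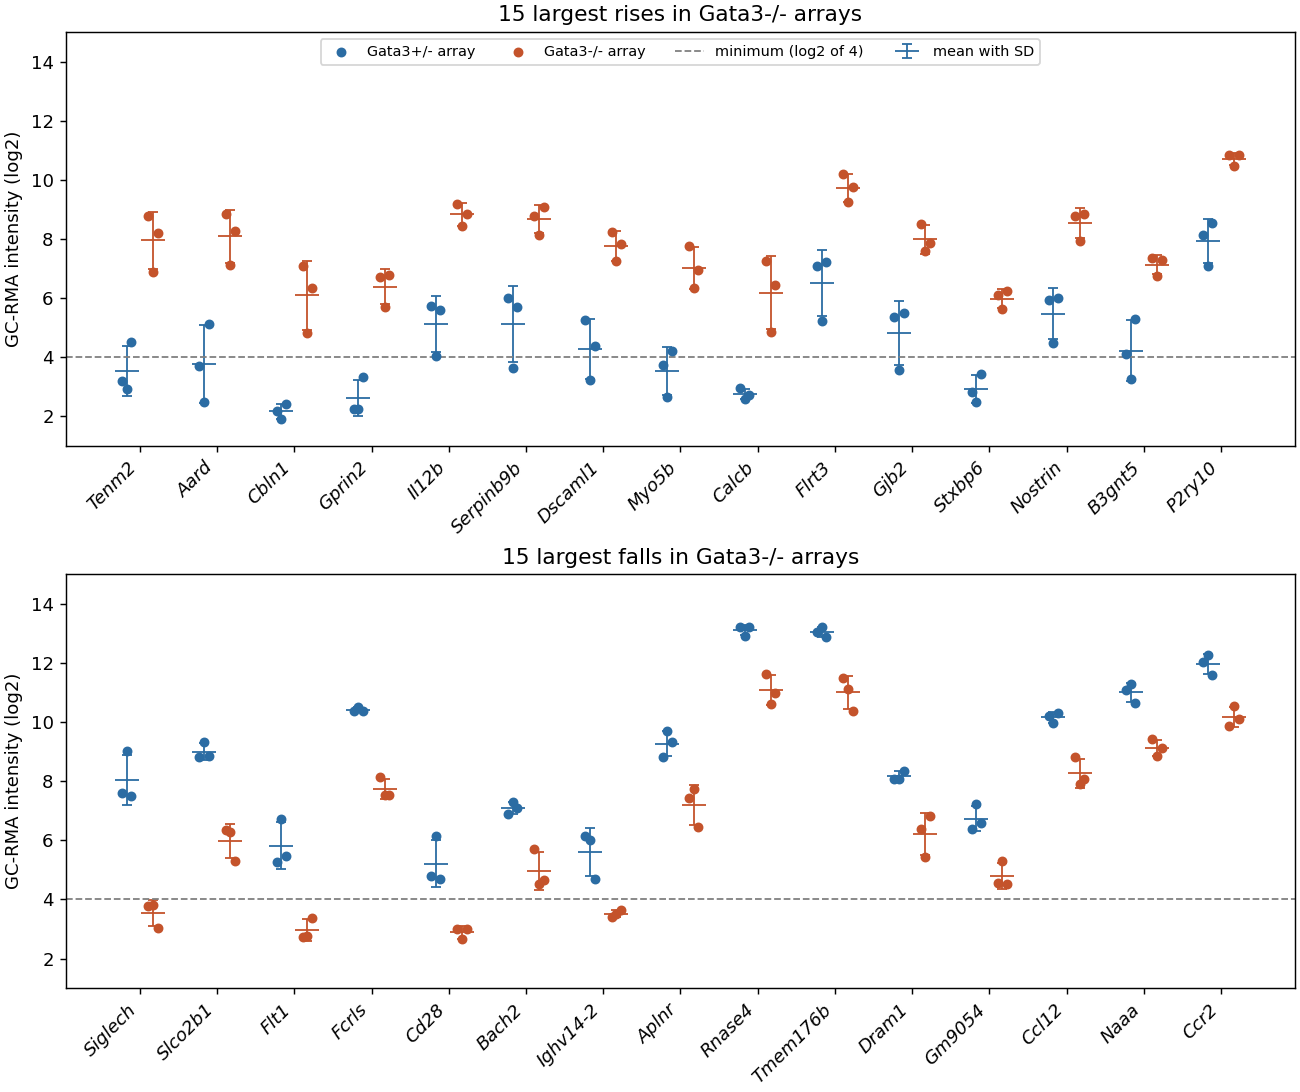
Log2 GC-RMA intensity of the 15 genes with the largest rises and the 15 with the largest falls, with a point per array, a bar for the mean ± SD of 3 arrays and a dashed line at the minimum of 4. In every gene shown the 3 Gata3-/- arrays lie apart from the 3 Gata3+/- arrays, as the selection required, and Siglech ranges from 7.50 to 9.02 in Gata3+/- arrays and from 3.04 to 3.81 in Gata3-/- arrays.

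By probe set, 878 of 20102 passed the threshold in limma, 452 higher and 426 lower, and 159 of the called genes changed at least 2-fold. The adjusted p-values of called genes lay between 0.0173 and 0.0499, and leaving out any 1 array left 0 to 4 genes called. All 543 kept their sign and an unadjusted p under 0.05 with limma in each of those 6 fits. That carries little weight, because the genes were selected on the same arrays. Without a filter 98 genes were called. No other probe set of Aplnr, Flrt3, Irf8, Kit or Zbtb46 passed, with differences of -1.03, 3.48, -0.71, 0.87 and 2.30.

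Most genes of the T lineage were not measurable on any array. Of 32 T-lineage genes named on the array, 10 passed the filter, and 21 never reached the minimum on any of the 6 arrays. Cd3e, a chain of the T-cell receptor complex, stood at 2.42 ± 0.01 in Gata3+/- and 2.45 ± 0.04 in Gata3-/- arrays, and Bcl11b, a T-lineage commitment factor, at 3.02 ± 0.24 and 3.27 ± 0.13. Ptcra, the pre-T-cell receptor chain, and Il2ra, an activation and progenitor marker, were under the minimum throughout. Among the 10 measured genes Cd1d1, which presents lipids to T cells, rose by 0.87 (SE 0.08), Cd28 fell, and 8 did not pass (adjusted over the list alone, 2 higher and 2 lower). Tox, a nuclear factor of T-cell development, stood at 7.43 ± 1.05 and 5.84 ± 1.38 (adjusted p = 0.322). Of 6 measured Notch targets Dtx1, which encodes a regulator of Notch signalling, fell by 1.41 (SE 0.16, adjusted p = 0.0289, 2 of 3 Gata3-/- arrays at the minimum) and 5 did not pass (1 lower adjusted over the list alone), Notch1 among them at 7.81 ± 0.38 and 7.72 ± 0.93. Neither list passed as a whole (camera adjusted p = 0.586 for T-lineage genes and 0.676 for Notch targets).

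Of 24 genes of granulocytes and monocytes 19 were measured. The granule genes Elane, Ctsg, Ngp, Ltf and Camp never reached the minimum, and S100a8 and S100a9, abundant in neutrophils, stood at 5.63 ± 1.80 and 5.61 ± 1.70 in Gata3+/- arrays, with differences of 2.37 (adjusted p = 0.265) and 2.63 (adjusted p = 0.186). The protease gene Prtn3 had a difference of -2.19 (adjusted p = 0.0850). These 8 genes were chosen after their values were seen. Csf1r, the receptor for macrophage colony-stimulating factor, stood at 14.55 ± 0.05 in Gata3+/- and 14.33 ± 0.08 in Gata3-/- arrays, and the lysozyme gene Lyz2 at 13.06 ± 0.36 and 12.94 ± 0.30. The list lay lower in Gata3-/- arrays (camera adjusted p = 0.0278, median -0.22), with 16 members negative and 3 positive, although 0 passed over all genes with limma (4 lower adjusted over the list alone). With an estimated correlation the adjusted p = 0.696. Cebpa, a myeloid transcription factor, had a difference of -1.18 (adjusted p = 0.0829) and Ly86 of -0.88 (adjusted p = 0.0617). Without Gata3+/- replicate 3 the camera adjusted p was 0.151 and without Gata3-/- replicate 2 it was 0.0730.

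Targets of p53, the stress-activated tumour suppressor, lay higher in Gata3-/- arrays (camera adjusted p = 0.00216, median 0.52), with 12 of 13 measured members positive. With an estimated correlation the adjusted p = 0.696. Zmat3, an RNA-binding p53 target, rose by 0.96 (SE 0.13) and 12 did not pass (5 higher adjusted over the list alone). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, had a difference of 1.28 (adjusted p = 0.0689) and Plk2 of 2.34 (adjusted p = 0.0690). Cell cycle genes lay lower (camera adjusted p = 0.00216, median -0.25), with 25 of 29 measured members negative. With an estimated correlation the adjusted p = 0.981. None of the 29 passed over all genes with limma (1 higher and 3 lower adjusted over the list alone), and the mitotic genes Aurka and Tpx2 had differences of -0.50 (adjusted p = 0.0508) and -0.43 (adjusted p = 0.0519).

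Genes of IL-7 and cytokine signalling lay higher in Gata3-/- arrays (camera adjusted p = 0.0357, median 0.34), with 9 of 12 measured members positive. With an estimated correlation the adjusted p = 0.696, and without Gata3-/- replicate 1 the camera adjusted p was 0.0978. Il7r rose by 1.20 (SE 0.19, adjusted p = 0.0371) and Stat5a, a transcription factor activated by the receptor, by 1.04 (SE 0.14, adjusted p = 0.0334), while 10 did not pass (5 higher adjusted over the list alone). Socs2 and Cish, feedback inhibitors induced by STAT5, had differences of 2.31 (adjusted p = 0.0551) and 1.86 (adjusted p = 0.0548).

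The other tested lists did not pass as a whole. Of 13 dendritic cell genes Zbtb46, a factor of conventional dendritic cells, rose by 1.89 (SE 0.35), Siglech and Irf8, a factor of dendritic cell and monocyte development, fell, and 10 did not pass (2 higher and 3 lower adjusted over the list alone). The camera adjusted p was 0.978, and the list's median (0.19) differed in sign from its mean (-0.02) and test. Of 16 multipotent progenitor genes Kit rose, Cd34, a surface marker of progenitors, fell by 0.88 and Mef2c, a factor of early lymphoid and myeloid cells, by 0.70, and 13 did not pass (3 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.813). The median of that list was -0.09, its mean 0.01 and its test downward. Of 12 B-lineage genes Cd24a, a surface antigen of immature cells, rose by 1.30 and Cd72, a B-cell coreceptor, fell by 1.25, and 10 did not pass (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.953). Of 10 natural killer and innate lymphoid genes the chemokine gene Ccl5 rose by 1.30 and Il18rap, an IL-18 receptor chain, fell by 0.98, and 8 did not pass (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.813).

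Of 10 mast cell and basophil genes Kit rose and 9 did not pass (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.231), and of 11 gamma-delta T genes Cd24a rose and 10 did not pass (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.962). None passed among 15 erythroid and megakaryocyte genes (camera adjusted p = 0.978; median -0.08, mean 0.04 and an upward test), 13 interferon response genes (0.813), 13 immediate early and heat shock genes (0.464), 11 hypoxia and glycolysis genes (0.586; 1 higher and 1 lower adjusted over the list alone) and 6 E protein and Id genes (0.831). The median of the 18 measured OP9 stromal genes was -0.65 (camera adjusted p = 0.464), but their mean level ran from 7.35 to 9.57 over the 6 arrays and was lowest on replicate 2 of both genotypes. Without Gata3+/- replicate 2 the camera adjusted p of that list was 0.0123 and without Gata3-/- replicate 3 it was 0.0179, and without Gata3+/- replicate 1 that of the immediate early list was 0.0340. Lists of 4 measured pluripotency genes, 4 Th2 genes and 3 sex chromosome genes were too small to test (adjusted over the list alone, 0 called, 1 lower and 3 higher). Pou5f1 and Nanog did not pass the filter, and Maf, a factor of Th2 cells and macrophages, had a difference of -0.48 (adjusted p = 0.0607).

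Among regulators of blood development, Spi1, the myeloid and lymphoid factor PU.1, stood at 12.47 ± 0.15 and 12.36 ± 0.15, and Ikzf1, a lymphoid zinc finger factor, at 12.08 ± 0.16 and 12.13 ± 0.28. Gata1, Gata2, Runx1, Runx3, Myb, Zbtb7b and Ebf1 did not pass either, with differences between -0.33 for Ebf1 and 0.81 for Runx3. Pax5, a B-lineage factor, was under the minimum on all arrays, and Tcf7 was not analysed here.

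**Figure D2:**
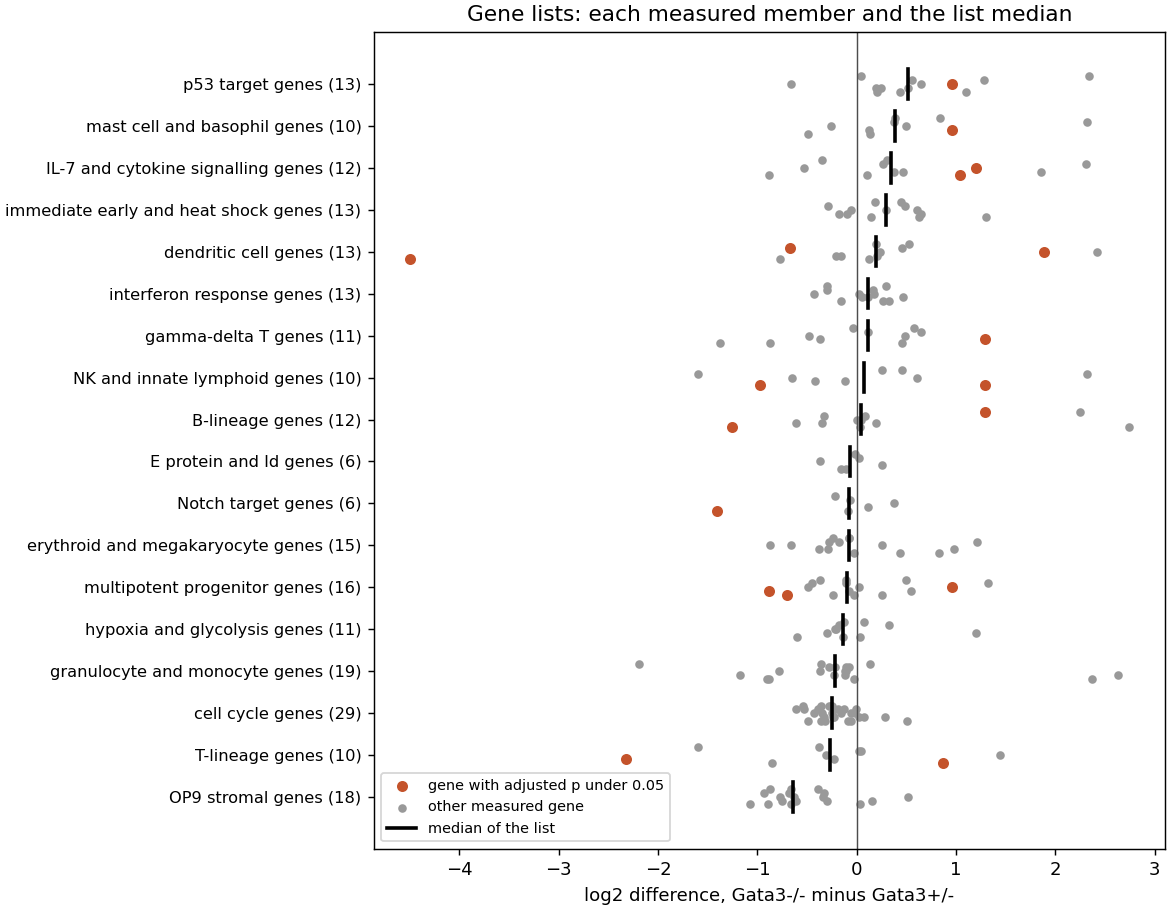
Log2 difference between Gata3-/- and Gata3+/- arrays (n = 3 each) for every measured member of the 18 tested lists, with the number of members in brackets, red points for genes with an adjusted p under 0.05 and a black bar for the list median. The medians run from -0.65 for OP9 stromal genes to 0.52 for p53 targets.

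The called genes were unevenly spread over the chromosomes, which was examined after the values were seen. Chromosome 11 held 94 of the 295 higher genes (31.9%) and 2 of the 248 lower genes, against 8.64% of the genes tested (two-sided Fisher's exact test for higher genes, adjusted over 21 chromosomes, p = 1.37e-29, in which genes are not independent). The median difference of its 889 genes was 0.33 and 90.4% of them lay above the median of the other genes. Tenm2, Il12b, Ccl5, Stat5a and Ccl12 are on this chromosome. On chromosome 6 a run of 131 neighbouring tested genes from Smarcad1 to Frmd4b had a median of 0.55, with 33 higher and 1 lower. On chromosome 14 a run of 53 genes from Ero1a to Ajuba had a median of -0.58, with 20 lower and 2 higher, and a run of 41 genes from Dcaf11 to Cab39l had a median of 0.40. The runs join all windows of 25 neighbouring genes whose median lay beyond every value in 1000 shuffles of gene order, which reached -0.41 and 0.42. Whole windows are joined, so the named ends of a run can hold genes outside the shift. On chromosome 6 the windows centred on Smarcad1 and Frmd4b had medians of -0.11 and 0.15. The Y-linked genes Kdm5d, a histone demethylase, and Eif2s3y, a translation factor, rose by 1.70 and 0.63, and Uty differed by 0.44 (adjusted p = 0.0835). Without chromosomes 6, 11, 14 and Y, 229 of 8550 genes were called, 93 higher and 136 lower, and the granulocyte and monocyte and the IL-7 lists each had a camera adjusted p of 0.0671.

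**Figure D3:**
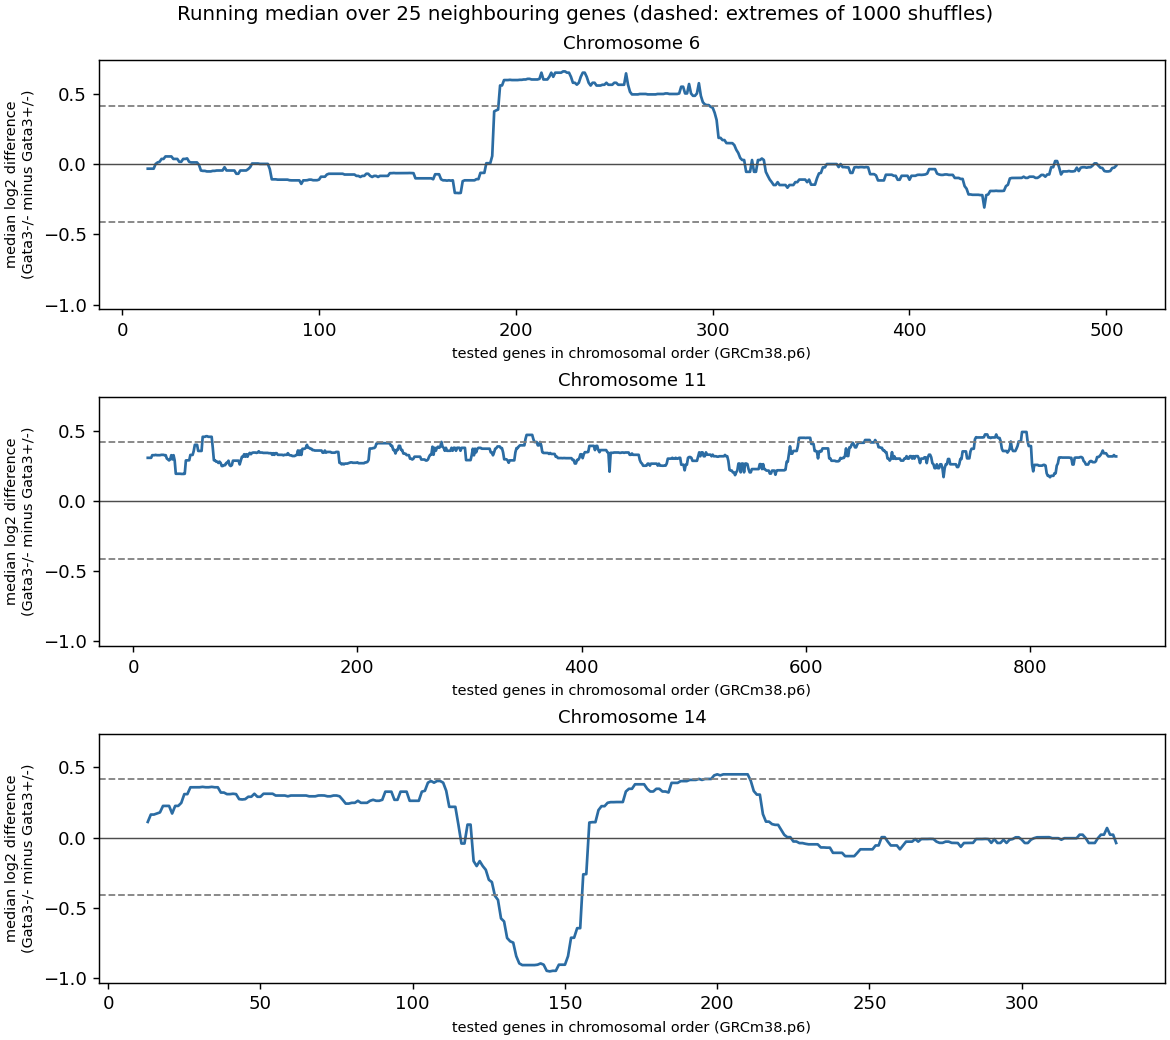
Running median of the log2 difference (Gata3-/- minus Gata3+/-) over 25 neighbouring tested genes along chromosomes 6, 11 and 14, in gene order of assembly GRCm38.p6, with dashed lines at the lowest (-0.41) and highest (0.42) values in 1000 shuffles of gene order. Chromosome 11 lies above 0 along its length, chromosome 6 rises in a run of 131 genes, and chromosome 14 falls in a run of 53 genes.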

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

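The fits without chromosomes 6, 11, 14 and Y and without both arrays numbered 2 were chosen after seeing the data; all others were planned. Of the probe sets and genes, 878 and 543 were called. The counts were 166 and 98 without a filter, 1349 and 824 with a variance trend and robust eBayes, 2075 and 1224 with array weights, 257 and 159 with a 2-fold minimum, 392 and 229 without chromosomes 6, 11, 14 and Y, and 4 and 3 without both arrays numbered 2. They stayed within 1.5 times under the stricter filter, quantile normalization, median centring and averaging per gene. Leaving out each array in turn left 0 to 9 probe sets and 0 to 4 genes, with 3578 to 4622 probe sets and 2043 to 2484 genes at an unadjusted p under 0.05. These fits hold fewer arrays. All 543 genes kept their sign in each, which carries little weight because they were selected on the same arrays. No value of a named gene reversed among those called. Of the 44 called named genes, 44 were called with quantile normalization, 40 with median centring, 1 without both arrays numbered 2 and 0 in every fit that left out an array. Gata3 stayed uncalled under every alternative run, with differences from -0.21 to 0.30.

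With the replicate block 498 probe sets and 298 genes were called, of which 295 and 181 were among those called without it, and 30 of the 44 called named genes were called. Deviations from the genotype mean correlated by 0.005, 0.695 and 0.429 for numbers 1, 2 and 3 across all tested probe sets. Gata3+/- array 1 correlated better with Gata3-/- array 3 (0.424). Deviations within a genotype cancel out over its arrays, so the shared deviation of the arrays numbered 2 itself raises correlations among the other arrays. These values therefore do not settle whether the arrays were paired. The arrays share a number, and no pairing is assumed. With the replicate block the OP9 stromal list had an adjusted p of 0.0136 and the immediate early list of 0.0368.

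Of 18 lists 4 were called, and 0 with an estimated correlation or with the directional test of fry. With an estimated correlation the adjusted p was 0.981 for the cell cycle and 0.696 for the p53, granulocyte and IL-7 lists, and with the directional test of fry 0.302 and 0.0748. The mixed test of fry, for change of members in either direction, gave adjusted p-values from 5.36e-06 for T-lineage genes to 0.582 for OP9 stromal genes. It gave 0.00117 for dendritic cell genes and 0.505 for interferon response genes. The granulocyte list had 0.0929 with array weights, and it and the IL-7 list had 0.0671 without chromosomes 6, 11, 14 and Y. Without a filter 21 lists were tested and 6 called, the added ones being the sex chromosome list (0.00573), too small to test with the filter, and the mast cell list. The mast cell list had 0.0326 without a filter and 0.0230 without those chromosomes, and the OP9 stromal list 0.0343 without both arrays numbered 2. Leaving out each array moved the adjusted p of the granulocyte list from 0.0135 to 0.151 (0.151 without Gata3+/- replicate 3 and 0.0730 without Gata3-/- replicate 2) and that of the IL-7 list from 0.0146 to 0.0978 (highest without Gata3-/- replicate 1). It moved the OP9 stromal list from 0.0123 to 0.944, with 0.0123 without Gata3+/- replicate 2 and 0.0179 without Gata3-/- replicate 3, and the immediate early list from 0.0340 (without Gata3+/- replicate 1) to 0.749. The causes of these changes were not tested. Values near the GC-RMA floor limit what can be said of dim genes.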

Other observations

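All tests, gene lists and single genes in this part were chosen after the results were seen, and the bounds they were read against were written down after the tests had been run. The called genes led to 3 lists, of mature dendritic cells, tissue macrophages and plasmacytoid dendritic cells, which are not independent evidence because they hold genes already seen to differ; 2, 1 and 8 of their genes are also in lists fixed earlier. Of 23 measured mature dendritic cell genes 22 had a positive difference (median 1.42) and 10 were higher, with 0 lower. Cd80 and Cd86, costimulatory ligands for T cells, rose by 1.65 (SE 0.20) and 1.15 (SE 0.18), and Rel, an NF-kappaB subunit on chromosome 11, rose by 1.58 (SE 0.20). The chemokine receptor gene Ccr7 had a level of 12.22 in Gata3+/- and 14.64 in Gata3-/- arrays (adjusted p = 0.108). Of 19 measured macrophage genes 16 had a negative difference (median -0.57) and 4 were lower, among them Gas6, a ligand of TAM receptors, which fell by 1.54 (SE 0.25), while Trem2, a lipid receptor, had a difference of -2.46 (adjusted p = 0.0508).

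Of 14 measured plasmacytoid dendritic cell genes 4 were lower, Siglech, Pacsin1, Irf8 and Tlr7, an RNA sensor, and 7 had a negative difference (median -0.06). Spib, a factor of that cell type and of B cells, went the other way, with a difference of 2.74 (adjusted p = 0.0652). Camera gave adjusted p-values over these 3 lists of 5.04e-12 for the mature dendritic cell, 1.13e-05 for the macrophage and 0.225 for the plasmacytoid list. With an estimated correlation the adjusted p was 0.136, 0.136 and 0.424, and with fry, which tests a list against no change and not against other genes, 0.00703, 0.00703 and 0.0332. Without chromosomes 6, 11, 14 and Y the mature dendritic cell list had a median of 1.18 over 19 genes and the macrophage list of -0.61 over 17.

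The shift of chromosome 11 was present on each array, with medians relative to genes elsewhere and to the Gata3+/- mean of 0.34 to 0.39 on Gata3-/- arrays and -0.09 to 0.06 on Gata3+/- arrays. Bias by intensity or gene length is argued against, since 10000 sets of genes from other chromosomes matched on both had medians of at most -0.0104, and so is a single deviating array, since the difference from the other chromosomes stayed at or above 0.31 whichever array was left out. A candidate explanation is that the stem cell lines differ in copy number. Only recurrence of the shifts was tested. For this, 4 runs were found anew on the arrays numbered 1 and 3 and read on those numbered 2. There the share of genes on the same side was 89.8% and 91.2% for 2 runs of 88 and 34 genes on chromosome 6. It was 96.6% for 29 genes on chromosome 11. For 51 lower genes on chromosome 14 it was 68.6%, between the bounds set, so recurrence of that run was not decided. In this order, the medians on the arrays numbered 2 against those on the other arrays were 0.78 against 0.44, 0.75 against 0.40, 0.47 against 0.36 and -0.69 against -0.50. Relative to the Gata3+/- mean, the 131 genes of the chromosome 6 run, selected for high medians, lay at 0.55 to 0.60 on Gata3-/- arrays, near the 0.58 of a change from 2 to 3 copies, chromosome 11 lay under that step, and the chromosome 14 run of 53 genes lay at -0.55 to -0.26, against -1.0 from 2 to 1 copies. Recurrence on other arrays of the same genotypes does not separate copy number from regional regulation that depends on Gata3. Both stay open as untested, since no DNA was measured.

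Both genotypes lacked most listed T-lineage transcripts and carried myeloid ones, with 9 to 11 of 32 T-lineage genes and 18 or 19 of 24 granulocyte and monocyte genes at the minimum on each array. Of 16 erythroid and megakaryocyte genes named on the array, 15 were measured. In Gata3+/- and Gata3-/- arrays their mean levels ran from 4.27 and 4.71 for Alas2 to 14.21 and 13.34 for Hbb-bh1, a globin gene, and 13.78 and 13.49 for Pf4. The T-cell receptor segments Trbv1 and Trgv4, outside the list, went the other way, at 8.99 or more and 7.38 or more on all 6 arrays. Other cells mixed into a majority of T-lineage cells that express the listed genes stay open for the list as a whole. The median of the 32 genes' highest levels on any array was 2.83. Its exact 95% interval, from 2.48 to 6.15, treats the listed genes as a random sample. The bound was 3, from a majority share, which lowers a level by at most 1 on the log2 scale. For the 21 genes that never reached the minimum of 4, the values argue against a majority of cells expressing them at 1 or more above it. Of the 32 genes, 10 passed the filter. The test of the median restates in part what was already known of the list. It followed others, on the share of the list measured, 31.25%, and on the CD3 genes, whose highest level was 2.74. These gave different verdicts as tests and bounds were changed after the results were seen. T-lineage cells of a stage that lacks these transcripts stay open as untested, since the sort markers are not given in the sources used here.

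The arrays numbered 2 deviated together in both genotypes, with 784 probe sets at least 0.5 from their genotype's mean in the same direction on both and 12 in opposite directions. The caveolin gene Cav1 stood at 3.21 on Gata3+/- array 2 and 3.27 on Gata3-/- array 2, against 6.96 to 8.68 on the other arrays, and the median deviation of the OP9 stromal list was -1.38 and -1.21. Less RNA from OP9 stroma is a possible explanation for the lower probe sets, which made up 80.9% of the 784. Such RNA would have been left over although the cells had been sorted by flow cytometry, with markers not given in the sources used here. The other 150 were higher, among them Trbv1, a T-cell receptor segment, and Cpa3, a mast cell protease. The share lay between the bounds set, so the test did not decide. On normalized arrays less stromal RNA can also raise probe sets of other cells, so this share cannot settle the question. A shared day or batch is not recorded in the labels, and no biological explanation was tested.

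The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by genotype called 878 probe sets and 543 genes, against at most 10 and 4 in the other splits, and 1 of the 10 splits reached each of those counts. It called 4 lists, against at most 5 in the other splits, and 3 of the 10 splits reached 4. For chromosome 11 the difference of medians was 0.36, against at most 0.17 in the other splits, and 1 of 10 reached it. The share of genes whose genotypes did not overlap was 33.6%. For each gene taken alone, chance gives 10%. Genes share deviations on these arrays, so the share in any split can lie far from 10%. It was not computed for the other splits, so no conclusion is drawn from this contrast.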
